A study of Mus musculus with 24 samples.

How the data were processed

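RNA from prostate, seminal vesicle, lung metastases and cell lines of Pten-deleted mice with or without active Notch1 was measured on 24 Agilent mouse arrays of 1 design (028005), on 3 slides of 8 arrays. Per the labels, sample RNA was amplified and coupled to the red Alexa dye and a universal reference RNA to the green Alexa dye, with no dye swap. The labels' protocol names a human reference RNA on this mouse array. Per the file headers, the images were read with Feature Extraction 11.0.1.1 under protocol GE2_1100_Jul11 and a grid of build mm9. The intensity values used were the raw median spot and local background signals, per the file headers. The design fixed in advance spoke of mean signals, but the files gave medians, which were used instead. The software's log10 ratio of red over green, background-subtracted and dye-normalized per the file headers, served as an alternative after conversion to log2. The authors also deposited a table of log2 ratios per spot. Its slope on the log2 scanner ratio was 0.922 to 1.00 per array (median 0.981, r = 0.938 to 0.997), which settled scale and direction. Column medians lay between -0.0166 and 0.0193, 5 values were missing, and the normalization behind that table is not given in the sources used here.

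Background was corrected with normexp (offset 50) and ratios were normalized within each array by loess, with control spots and outlier spots at weight 0, in limma 3.58.1 under R 4.3.3 with data.table version 1.17.8. Control spots were then left out (59305 spots remained, of 55681 probes) and spots of a probe averaged. No spot was saturated. Probes were named through a RefSeq gene table of assembly GRCm38.p6 by accession, which gave 26582 probes 1 of 20145 symbols, while 29099 kept the name in the files. No coordinates are given because the grid build differs from that assembly. A probe entered a fit when its sample channel was well above background on arrays of at least 2 samples of the fit. Each gene was represented by the probe with the highest mean sample signal, and other probes of named genes are given where they disagree. Arrays labelled as technical replicates of a sample were averaged and counted once.

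Differences of log2 ratios were tested with lmFit and eBayes with an intensity trend, with Benjamini-Hochberg adjustment at 0.05. The 6 primary samples shared a fit, as did the 4 PB-Pten-NICD primary tumours and 7 metastases, and the 3 lines and 7 metastases. Metastases were set against the equally weighted mean of both primary groups and against each. The labels do not say whether samples of a group came from separate animals, apart from the metastases, so p-values measure the spread between these samples, which may be technical. All adjusted p-values of genes are from limma, and ± in a log2 difference is its standard error. Gene lists (22 lists, 280 of 288 genes on the array, no gene in more than 1 list) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. With an estimated correlation 0 lists passed in any comparison. Where a probe was not well above background on any array of a group, the fold is a bound, from the bright group's mean and, in the dim group, the higher of the probe's signal and the lowest signal well above background, per channel after loess and Aquantile scaling. It is open to dye bias. Medians of lists use fitted values of such genes, and with these genes at their bounds 0 of 44 list calls had a median of the other sign. Array position and slide were compared through correlations of log2 ratios over probes.

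The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 highest and 8 lowest called genes with a symbol whose samples did not overlap between groups, up to 4 called members of each list that passed, and 16 genes of interest in every comparison, and for each cell line the 5 highest and 5 lowest genes, of which a few are given. Other list members were named after their values were seen. Alternatives were other background corrections, normalizations, filters, probe rules, fits, blocks, a lung marker covariate and the omission of each sample. Averaging by slide position, which left out the positions that metastasis 7 shared with PtNI-SV, and merging metastases of matching profiles were added after the data were seen.

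The pipeline was tested on simulated data with known changes, in 20 draws per comparison. At a log2 change of 2, 86.3% of changed genes were recovered for PB-Pten-NICD against PB-Pten prostate, 88.3% for seminal vesicle against prostate, 94.9% for metastases against primary tumours, 84.6% and 83.0% against prostate and seminal vesicle alone and 89.7% for cell lines against metastases. At a log2 change of 1 the shares were 9.45%, 8.75%, 44.1%, 20.8%, 18.5% and 30.9%. Of all calls 10.7%, 11.6%, 5.47%, 5.09%, 5.19% and 5.37% were false. A list left unshifted was called in at most 15% of draws (camera at the preset correlation, unadjusted p under 0.05). The simulated noise was independent between genes and between samples. It held no matching metastases, slide differences or correlated list genes, so these rates may not hold for the real data.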

Results

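Gene expression was measured on 24 Agilent 2-colour mouse arrays, each hybridised with RNA of a sample in red and a common reference RNA in green. The arrays covered 16 samples from a mouse model of prostate cancer. In PB-Pten mice a probasin promoter drives Cre recombinase, which deletes floxed Pten, a lipid phosphatase that restrains PI3K signalling. PB-Pten-NICD mice also express the intracellular domain of Notch1 (NICD), the active form of that receptor, after Cre recombination. The labels gave 2 PB-Pten prostates, 2 PB-Pten-NICD prostates, 2 PB-Pten-NICD seminal vesicles and 7 lung metastases. They also gave 3 cell lines derived from a PB-Pten-NICD seminal vesicle tumour (PtNI-SV), a prostate tumour (PtNI-Pro) and a lung metastasis (PtNI-Met). The strain tag of the 2 PB-Pten prostates read PB-Pten-NICD while their titles read PB-Pten, and the titles were followed. Of the probes, 41.8% to 88.7% (median 74.9%) were well above background in the sample channel of an array. The PB-Pten-NICD seminal vesicle arrays were the dimmest primary samples, at 45.5% to 58.8%, and the number of arrays limits the precision of every comparison.

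The arrays of slides 2 and 3, which held metastases 3 to 7 and the cell lines, did not follow their labels. Arrays labelled as technical replicates of 1 sample correlated at r = -0.22 to 0.68 (median 0.52, 8 pairs, across 51876 probes, which are not independent replicates). Arrays at the same position on slides 2 and 3 carried different labels and correlated at 0.79 to 0.94 (median 0.91). Each of the 8 arrays of slide 2 had its best match on slide 3 at the same position (exact permutation p = 2.48e-05, one-sided), and 0 of the 16 arrays matched best with their labelled replicate. The averaged profiles of metastases 3 and 5 correlated at 0.93 and those of metastases 4 and 6 at 0.94, so these may not be separate animals, in which case p-values that count 7 metastases would be too small. The match also crossed groups, with arrays of metastasis 7 and PtNI-SV at r = 0.91 and 0.91, and joined the lines PtNI-Pro and PtNI-Met at 0.93 and 0.79. No array was moved to another group. Every value below for metastases 3 to 7 or a cell line is that of the arrays labelled so, and values from slide 1, which held all primary samples and metastases 1 and 2, are given for part of the genes and lists. Array pairs of the same dye orientation correlated as low as r = -0.42, in 9 pairs under -0.3. The reference channels of all 24 arrays resembled each other (lowest median rho 0.873), so the direction of the ratios was kept. On array 2 of metastasis 7 the sample channel resembled other reference channels more than other sample channels (median rho 0.824 against 0.651). The same held for array 2 of PtNI-SV (0.842 against 0.694), PtNI-Pro and PtNI-Met, and for metastasis 1. Array 2 of metastasis 7 and of PtNI-SV had negative median r with the other arrays (-0.21 and -0.25).

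**Figure D1:**
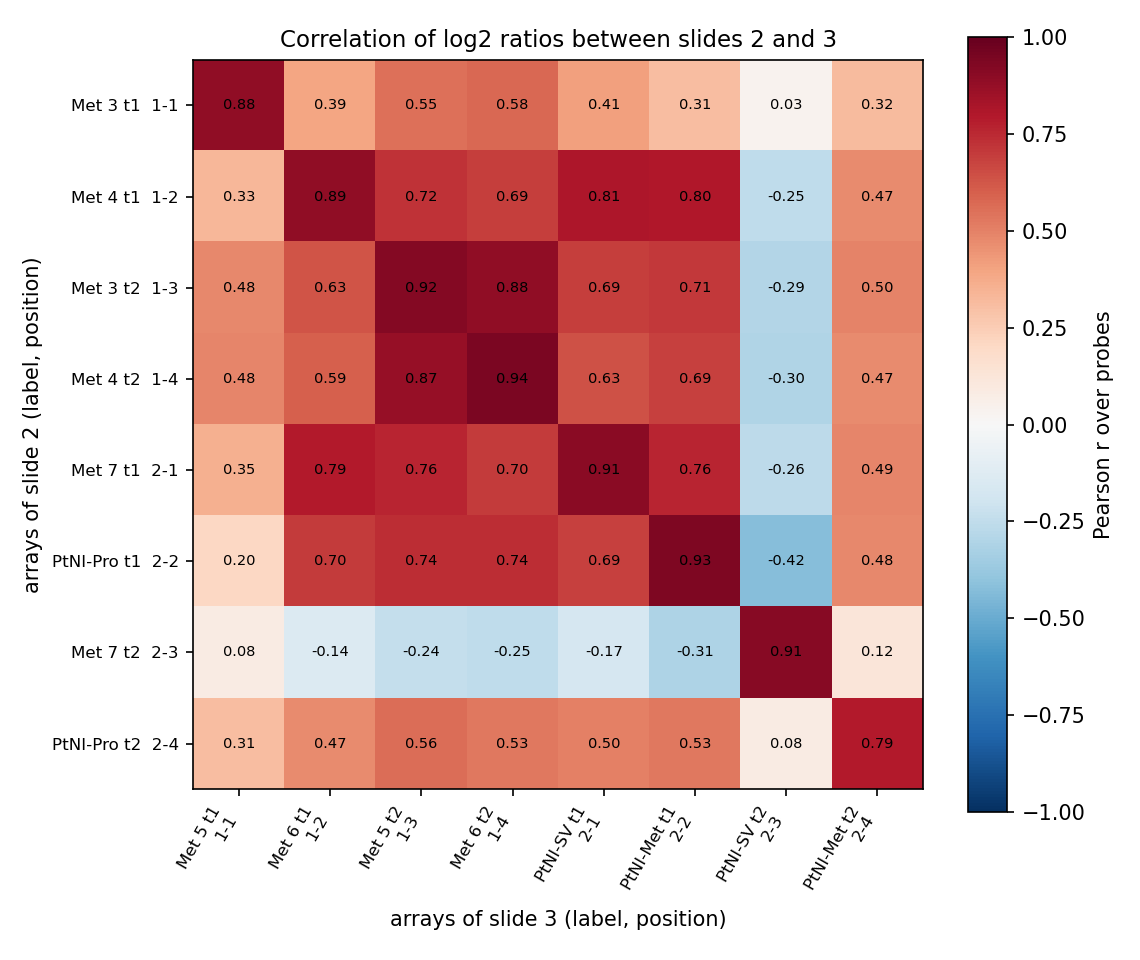
Pearson correlation, across probes, of the log2 ratio of sample to reference between each array of slide 2 (vertical axis) and each array of slide 3 (horizontal axis), with labels and slide positions (Met, lung metastasis; t1 and t2, technical replicates 1 and 2). The 8 values on the diagonal, from arrays at the same position, lie between 0.79 and 0.94 and are the highest for both arrays of each pair.

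The comparison of PB-Pten-NICD with PB-Pten prostate asked what active Notch1 added in prostates lacking Pten. Among the genes higher in the PB-Pten-NICD prostates were 3 of the 6 measured genes of the seminal vesicle secretory list (adjusted p = 0.290 for the list with an estimated correlation). Pate4, a secreted protein of seminal vesicle fluid, was at least 48.7-fold higher, with a log2 ratio to reference of 6.10 ± 1.05 against 0.07 ± 0.11 (SD, n = 2 each, adjusted p = 0.00929). Spink8, of the Kazal serine protease inhibitor family, rose by 5.72 ± 0.51 (log2 difference ± SE, adjusted p = 0.00285) and Wfdc15b by 4.70 ± 0.56 (adjusted p = 0.0233). Reg3b, a secreted C-type lectin with antibacterial activity, was the 1 gene that fell, by -4.19 ± 0.36 (adjusted p = 0.00272).

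The other genes that rose were Cyp4a12a, a fatty acid hydroxylase (4.26 ± 0.35), Svs2, a main protein of the copulatory plug (at least 10.6-fold, adjusted p = 0.00272), Pate6 (3.72 ± 0.37), Svs5 (3.33 ± 0.37) and Elf5, an epithelial ETS transcription factor (2.68 ± 0.35, adjusted p = 0.0467). A second Svs2 probe differed by 0.00. In all, 8 genes rose and 1 fell among 30556 tested (limma, Benjamini-Hochberg, 642 genes at an unadjusted p under 0.05). Of the 6 measured genes of the seminal vesicle secretory list, 3 rose over all genes and 4 when adjusted over the list alone. Svs4 was the additional gene, at 3.51 ± 0.63, and Svs3b and Sva differed by 0.13 and -0.02. The list's median difference was 3.42 (camera adjusted p = 1.08e-16), with adjusted p = 0.290 with an estimated correlation and 0.0844 by fry, in which 0 lists passed in this comparison.

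Of the 10 measured Notch pathway targets, 0 passed over all genes in limma and 2 were higher when adjusted over the list alone. Nrarp, a feedback inhibitor induced by Notch, differed by 1.88 ± 0.41 (adjusted p = 0.572), Notch3 by 0.99 ± 0.36 and Hes1 by -0.50 ± 0.37. Hey2 and Hey1 were not above background in the PB-Pten prostates, with bounds of at least 1.85-fold and 1.40-fold that did not pass. The list's median was 0.34 (camera adjusted p = 0.00415, and adjusted p = 0.324 with an estimated correlation). Lists of other cell types also passed as higher. The medians were 0.45 for smooth muscle (9 genes, such as Actg2 at 0.94), 0.28 for endothelium (10 genes, Esam at 0.83), 0.35 for adipocytes (8 genes, Cfd at 2.22 and Fabp4 at 1.44, 2 higher when adjusted over the list alone) and 0.88 for red blood cells (5 genes, Hba-a1 at 0.88). Their camera adjusted p were 0.00415, 0.0210, 0.0210 and 0.0239, and with an estimated correlation the adjusted p was 0.501 for smooth muscle and 0.324 for the other lists. The smooth muscle mean was 0.42 with all samples, -0.026 without PB-Pten-NICD prostate 1 and 0.87 without prostate 2. The prostate luminal list passed in the lower direction (12 genes, median -0.08, mean -0.42, camera adjusted p = 0.0428), with Tmprss2 at -1.82, Hoxb13 at -1.48 and Nkx3-1, which differed in the other direction, at 0.82. It had an adjusted p = 0.324 with an estimated correlation, 0 genes past the test over all genes and 2 lower when adjusted over the list alone.

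The log2 ratio of Pten was -1.45 and -1.10 in the PB-Pten prostates, -1.17 and -2.09 in the PB-Pten-NICD prostates and -2.04 and -2.37 in the seminal vesicles. Notch1 was at 0.25 ± 0.01 and 0.58 ± 0.03 (SD, n = 2) in the PB-Pten and PB-Pten-NICD prostates. Where the Pten and Notch1 probes lie relative to the deleted and the expressed parts is not known here, so these values do not check the labels. Between the prostates Pten differed by -0.36 ± 0.39 and Notch1 by 0.33 ± 0.33, and second probes of these genes differed by 0.69 and 0.88. Ar, the androgen receptor, differed by 0.00 ± 0.35, Pbsn by 0.13 ± 0.37, Krt5 by -0.27 ± 0.37, Cdh1 by -0.36 ± 0.34, Vim by 0.67 ± 0.40 and Mki67 by 0.06 ± 0.38, all with an adjusted p of 1.

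The count of 9 genes was 5 without either seminal vesicle sample, 26 and 35 without PB-Pten prostate 1 and 2, and 48 and 35 without PB-Pten-NICD prostate 1 and 2. In data simulated on these 6 samples 10.7% of calls were false, above the nominal 5%.

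**Figure D2:**
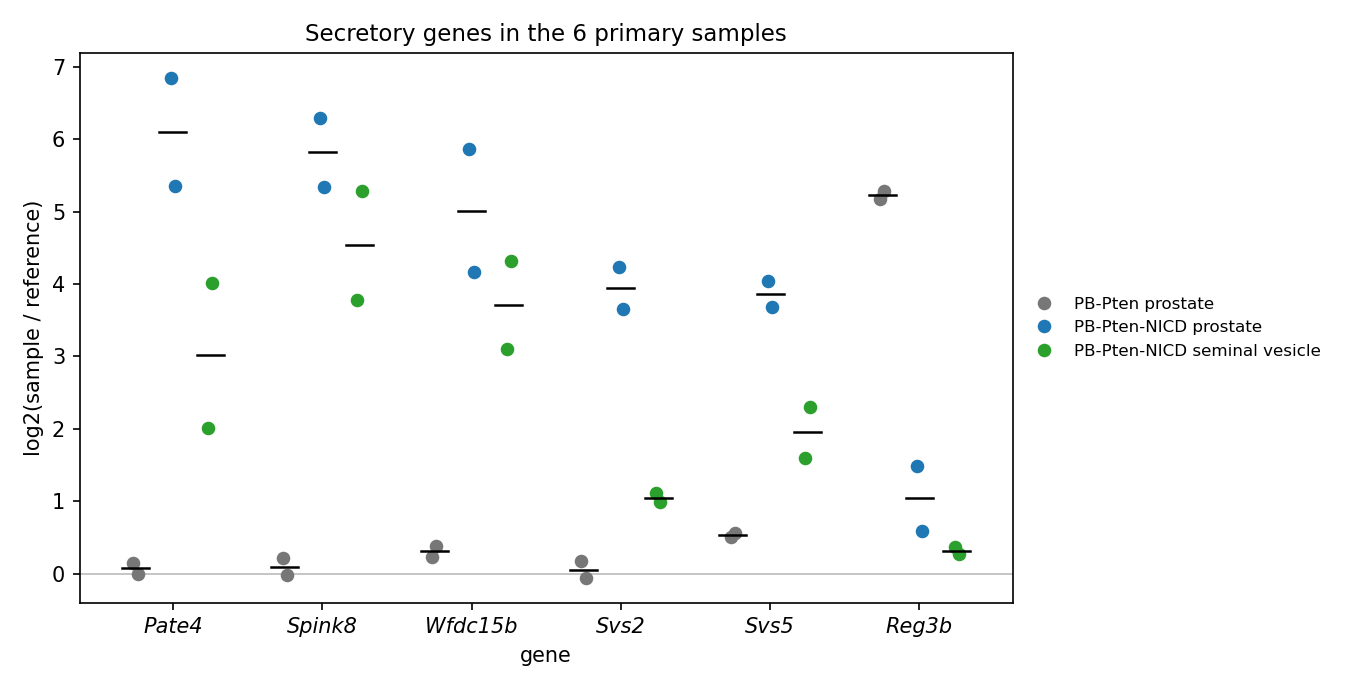
Log2 ratio of sample to reference (vertical axis) of 6 genes (horizontal axis) in the 2 PB-Pten prostates, 2 PB-Pten-NICD prostates and 2 PB-Pten-NICD seminal vesicles. Each point is a sample and each bar a group mean. Pate4 averaged 0.07 in the PB-Pten and 6.10 in the PB-Pten-NICD prostates, and Reg3b 5.23 and 1.04.

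The comparison of PB-Pten-NICD seminal vesicle with PB-Pten-NICD prostate set tumours of 1 genotype at different sites against each other. Cyp2f2, a cytochrome P450 enzyme, fell by -6.17 ± 0.34 (log2 difference ± SE, adjusted p = 0.000104) in the seminal vesicles, from a ratio of 6.05 ± 0.29 to -0.12 ± 0.15 (SD, n = 2 each). Crisp1, a secreted protein of the male tract that binds sperm, was at least 37.5-fold lower (adjusted p = 0.0415), although the prostates themselves spread widely (5.93 ± 3.11). Akr1b7, an aldose reductase family enzyme, was at least 29.6-fold lower and Cxcl17, a mucosal chemokine, at least 12.3-fold lower. Hoxb13, a homeobox gene of the prostate lineage, was at least 7.48-fold lower (adjusted p = 0.0283).

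Further genes that fell were Gpx3, a secreted glutathione peroxidase (-4.11 ± 0.70), Anxa1, annexin A1 (-3.23 ± 0.51, measured in 1 of the prostates, a second probe at -2.91), Rnf186 (at least 7.39-fold), Svs2 (-2.89 ± 0.33, a second probe at -0.40), Dcn, the matrix proteoglycan decorin (-2.81 ± 0.42) and Fabp4, a fatty acid carrier of adipocytes (at least 3.83-fold). Higher in the seminal vesicles were Btnl5-ps (2.81 ± 0.44), the prolyl isomerase Pin1 (2.44 ± 0.36), Olfr658 (2.35 ± 0.40), Fsd1l (2.19 ± 0.38), Plaat3 (2.16 ± 0.34), Zfp457 (2.05 ± 0.22), Rgs20 (2.03 ± 0.34) and Btbd16 (1.98 ± 0.34). In the sample channel alone Pin1 differed by 2.44 but Zfp457 by 0.28 and Rgs20 by 0.37, and second probes of Pin1, Zfp457 and Rgs20 differed by 0.48, -0.55 and 0.08. In total 53 genes rose and 52 fell (3111 at an unadjusted p under 0.05).

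The secretory list that was higher in the PB-Pten-NICD prostates was lower in the seminal vesicles of that genotype. Of its 6 measured genes 1 fell over all genes and 4 when adjusted over the list alone, with Pate4 at -3.08 ± 0.63 (adjusted p = 0.0735), Svs4 at -2.14 and Svs5 at -1.91 (median -2.02, camera adjusted p = 3.96e-06, and adjusted p = 0.367 with an estimated correlation). Both comparisons used the same 2 PB-Pten-NICD prostates. Of 10 interferon response genes 0 passed over all genes and 7 were lower when adjusted over the list alone, among them Ifit3 (-2.41 ± 0.51), Oasl2 (-1.81 ± 0.37) and Ifit1 (at least 2.00-fold). The interferon list's median was -1.07 (camera adjusted p = 2.98e-09, and adjusted p = 0.367 with an estimated correlation). Of 20 epithelial genes 0 passed over all genes and 3 were lower when adjusted over the list alone, with Cldn3 at -1.72, Dsp at -1.58 and Cdh1 at -1.24 ± 0.34 (median -0.79, camera adjusted p = 1.50e-05, and adjusted p = 0.388 with an estimated correlation).

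Basal epithelial genes (12 genes, median -0.51, 0 lower over all genes and 2 when adjusted over the list alone) included Krt5 at -1.99 ± 0.37 (adjusted p = 0.0563) and Lamc2 at -1.91 ± 0.35. Squamous genes (13 genes, median -0.40) included Krt6a at -1.39 and Krt13 at -1.20. Their camera adjusted p were 0.00121 and 0.0327, and both had an adjusted p = 0.388 with an estimated correlation. Other marker lists that passed were lower, with adipocytes at a median of -0.40 (1 of 8 genes lower, 2 when adjusted over the list alone, camera adjusted p = 0.00305), smooth muscle at -0.44 (camera adjusted p = 0.0327, Acta2 at -1.20) and lung epithelium at -0.16 (camera adjusted p = 0.0293). Myeloid and red blood cell markers lay the other way, at medians of 0.51 and 0.65, and did not pass (camera adjusted p = 0.0789 for myeloid cells, and higher for red blood cells). In the lung epithelium list 1 of 14 genes fell, Cyp2f2, or 3 when adjusted over the list alone, with Abca3 at -1.66 and Hopx at -1.61. The list was not tested without Cyp2f2. The adjusted p was 0.367 with an estimated correlation for adipocytes and lung epithelium and 0.445 for smooth muscle. By fry 1 list passed, lung epithelium (adjusted p = 0.0147). The smooth muscle mean, -0.36 with all samples, turned to 0.087 without PB-Pten-NICD prostate 1 and was -0.81 without prostate 2. Outside the lists that passed, Ar differed by -0.02 ± 0.35, Nrarp by -1.38 ± 0.41, Hey1 by 0.23 ± 0.28, Zeb1 by 0.39 ± 0.31 and Vim by -0.60 ± 0.40, with adjusted p from 0.212 to 0.991.

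The count of 105 genes was 1 without seminal vesicle 1 or 2, 60 and 694 without PB-Pten-NICD prostate 1 and 2, and 637 and 724 without PB-Pten prostate 1 and 2. It was 0 when both channels had to be above background on every array (73 of the 105 still tested) and 31 (1 higher, 30 lower) in the sample channel alone, and in simulated data 11.6% of calls were false.

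The comparison of lung metastases with PB-Pten-NICD primary tumours asked what set the metastases apart from prostate and seminal vesicle tumours. In the samples labelled lung metastasis 9 of 22 mesenchymal and matrix genes rose, while 6 of 20 epithelial and 3 of 8 seminal vesicle secretory genes fell. With an estimated correlation these lists had adjusted p = 0.400, 0.332 and 0.332. With arrays averaged by slide position 0 genes of these lists passed over all genes. Sparc, a matrix glycoprotein, rose by 3.47 ± 0.54 (log2 difference ± SE, adjusted p = 0.0126), from -4.20 ± 0.57 (SD, n = 4) to -0.73 ± 1.18 (SD, n = 7). Vim, the intermediate filament vimentin, rose by 3.03 ± 0.61 (adjusted p = 0.0244) and Fn1, fibronectin, by 2.94 ± 0.54 (adjusted p = 0.0187). Mmp7, a matrix-degrading protease of epithelial cells, fell by -4.98 ± 0.60 (adjusted p = 0.00507) and Krt5, a keratin of basal cells, by -1.69 ± 0.22 (adjusted p = 0.00878). On slide 1 alone, with metastases 1 and 2, the differences were 4.24 for Sparc, 3.86 for Vim and 3.51 for Fn1, and Mmp7 was at least 54.3-fold lower.

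Of 22 mesenchymal and matrix genes 9 rose over all genes and 15 when adjusted over the list alone (median 1.49, camera adjusted p = 0.00992, and adjusted p = 0.400 with an estimated correlation). On slide 1 12 of 20 rose (median 2.26, camera adjusted p = 2.44e-05, and adjusted p = 0.376 with an estimated correlation), and by slide position 0 of 22 passed over all genes (median 1.67, camera adjusted p = 0.0170, and adjusted p = 0.629 with an estimated correlation). Arrays labelled as 1 sample differed widely, with Vim at 0.036 and -4.44 in metastasis 3 and at -2.91 and 2.10 in metastasis 7, and both arrays of metastases 4 and 6 lay between -4.25 and -3.24. Besides Sparc, Vim and Fn1 the genes that rose included Postn, periostin (at least 6.04-fold), and Col1a1 (2.94 ± 0.35). The basement membrane collagen Col4a1 (3.36 ± 0.92), the peptidase Cpe (3.36 ± 0.53), the tetraspan protein Tm4sf1 (3.30 ± 0.57) and Col6a2 (2.96 ± 0.72) also rose. Of 9 transcription factors of epithelial-mesenchymal transition (EMT) 5 rose over all genes and 7 when adjusted over the list alone. They included Snai1 (at least 2.14-fold), Zeb1 (1.09 ± 0.30), Zeb2 (0.89 ± 0.21) and Twist2 (0.91 ± 0.22, but -0.03 in the sample channel alone). The EMT list's median was 0.91 (camera adjusted p = 0.000223, and adjusted p = 0.332 with an estimated correlation). On slide 1 Snai1 was at least 7.83-fold higher and Zeb1 and Zeb2 were higher by 1.73 and 1.12, while Twist2 was not above background in metastases 1 and 2 and did not pass (adjusted p = 0.243). By slide position 0 of 9 EMT genes passed over all genes and 6 were higher when adjusted over the list alone (median 0.81, camera adjusted p = 0.000340, and adjusted p = 0.271 with an estimated correlation).

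Of 20 epithelial genes 6 fell over all genes and 8 when adjusted over the list alone, among them Elf3 (-1.57 ± 0.43), the tight junction genes Cldn4 (-1.37 ± 0.39) and Ocln (-1.08 ± 0.21) and the epithelial transcription factor Grhl2 (-1.04 ± 0.29). Their median was -0.91 (camera adjusted p = 1.48e-06, and adjusted p = 0.332 with an estimated correlation). Cdh1, E-cadherin, differed by -1.40 ± 0.44 (adjusted p = 0.0661) and Epcam by -1.06 ± 0.52 (adjusted p = 0.208), and on slide 1 Cdh1 was at least 4.28-fold lower and Epcam lower by -2.53 (adjusted p = 0.000581 and 0.00671). Cdh1 was at 0.14 and 1.81 on the arrays of metastasis 3 and at 2.14 and 3.03 on those of metastasis 4. It was at -0.09 and 0.13 in metastases 1 and 2 and between 1.70 and 3.24 in the primary tumours. Epcam was at 1.03 and 1.88 in metastasis 3 and 1.65 and -0.95 in metastasis 7 (primary tumours 0.91 to 2.66). Krt8 was at -3.91 and 2.25 in metastasis 3 (primary tumours -0.39 to 1.56). These genes were therefore not low on every array labelled lung metastasis. On slide 1 12 of the 20 epithelial genes fell (median -1.52, camera adjusted p = 2.55e-14, and adjusted p = 0.305 with an estimated correlation). By slide position 0 of the 20 passed over all genes and 8 were lower when adjusted over the list alone (median -0.98, camera adjusted p = 1.39e-07, and adjusted p = 0.271 with an estimated correlation). Further genes that fell were Spink8 (-4.37 ± 0.67), Pate4 (-3.90 ± 0.52), Wfdc15b (-3.86 ± 0.53), Reg3g (-3.01 ± 0.48), Svs5 (-2.52 ± 0.30), Svs4 (-2.16 ± 0.38), the zinc transporter Slc39a8 (-3.78 ± 0.59), Clca3a2 (-3.10 ± 0.45), Capn13 (-3.03 ± 0.29) and Tspan1 (-2.94 ± 0.43). Of 8 seminal vesicle secretory genes 3 fell over all genes and 4 when adjusted over the list alone (median -0.31, mean -1.14, camera adjusted p = 0.00126, and adjusted p = 0.332 with an estimated correlation). Of 14 squamous genes 1 fell, Krt6b (-0.94 ± 0.23), and 1 when adjusted over the list alone (median -0.33, camera adjusted p = 0.0356, and adjusted p = 0.332 with an estimated correlation).

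Of 22 proliferation genes 6 rose over all genes and 12 when adjusted over the list alone, among them Rrm2, a subunit of ribonucleotide reductase (1.70 ± 0.39), Cdc20 (1.56 ± 0.37), Mcm5 (1.47 ± 0.31) and Ube2c (1.39 ± 0.34). Mki67 differed by 0.75 ± 0.31 (adjusted p = 0.138). Of 12 hypoxia and glycolysis genes 3 rose, Ldha (1.81 ± 0.40), Ndrg1 (1.67 ± 0.45) and Pgk1 (1.54 ± 0.43), and 7 when adjusted over the list alone. The medians were 0.74 and 0.94 (camera adjusted p = 8.08e-06 and 0.00126), and both lists had an adjusted p = 0.332 with an estimated correlation. Of 11 immediate early genes 0 passed over all genes or when adjusted over the list alone, with Egr1 at 1.36 ± 0.42 (median 0.56, camera adjusted p = 0.0356, and adjusted p = 0.332 with an estimated correlation). On slide 1 the differences of Rrm2, Cdc20, Ldha and Ndrg1 were 1.17, 0.78, 1.38 and 0.34, and none of these 4 passed there. The proliferation list did not pass on slide 1 (median 0.51, 0 of 20 genes in limma over all genes or over the list alone, camera adjusted p = 0.0735), and the hypoxia list had 1 of 11 genes higher (median 0.37, camera adjusted p = 0.0432, and adjusted p = 0.498 with an estimated correlation). Of the immediate early genes 2 of 9 were higher on slide 1 over all genes and 4 when adjusted over the list alone (median 0.64, camera adjusted p = 0.0279, and adjusted p = 0.498 with an estimated correlation). By slide position 0 genes of these 3 lists passed over all genes, and the immediate early list did not pass (camera adjusted p = 0.0559).

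Among Notch pathway targets Myc rose (1.13 ± 0.29), 1 of 12 genes over all genes and 4 when adjusted over the list alone, while Heyl, not above background in the primary tumours, had a bound of at least 2.53-fold (adjusted p = 0.0938), and Hey1 differed by 1.46 ± 0.46 (adjusted p = 0.0653), Hes1 by 0.42 ± 0.31 and Nrarp by 0.35 ± 0.49. The list did not pass (median 0.38, camera adjusted p = 0.571). On slide 1 the Notch list passed, with 3 of 12 genes higher (median 0.40, camera adjusted p = 0.0279, and adjusted p = 0.305 with an estimated correlation), and Heyl was at least 8.33-fold higher (adjusted p = 0.000467). Endothelial markers passed there too, with 3 of 11 genes higher (median 0.51, camera adjusted p = 0.00798, and adjusted p = 0.305 with an estimated correlation). Prostate luminal genes did not pass as a list (median -0.34, camera adjusted p = 0.0576), but 3 of 14 fell over all genes and 3 when adjusted over the list alone, namely Hoxb13 (-1.25 ± 0.21), Pbsn (-0.68 ± 0.17) and Nkx3-1 (-0.58 ± 0.13). Hoxb13 was itself lower in the seminal vesicle than in the prostate tumours. Against the seminal vesicles alone 0 of the 14 fell over all genes or when adjusted over the list alone (median 0.01). By fry 9 lists passed, among them prostate luminal and basal epithelial genes (adjusted p = 0.0334 each), which camera left out, and by slide position 0 lists did (smallest adjusted p 0.0606). Ar differed by -0.67 ± 0.26 (adjusted p = 0.115), Pten by 0.83 ± 0.30, Notch1 by -0.23 ± 0.44, and Trp63 by 0.44 ± 0.26. Lung epithelium markers did not pass as a list (median -0.06, camera adjusted p = 0.480), with Lamp3 higher (0.98 ± 0.23) and Cyp2f2 (-2.11 ± 0.43) and Sftpd (-1.34 ± 0.30) lower, 1 higher and 3 lower when adjusted over the list alone. Cyp2f2 was also lower in the seminal vesicle than in the prostate tumours, so its fall from the mean of both groups came from the prostates. On slide 1 the red blood cell markers had a median of 4.41 in metastases 1 and 2 (camera adjusted p = 0.0279, and adjusted p = 0.487 with an estimated correlation). The prostate luminal list passed there as lower (median -0.68, camera adjusted p = 0.0279, and adjusted p = 0.327 with an estimated correlation). Of its 10 genes 1 fell over all genes, and 4 fell and 1 rose when adjusted over the list alone.

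**Figure D3:**
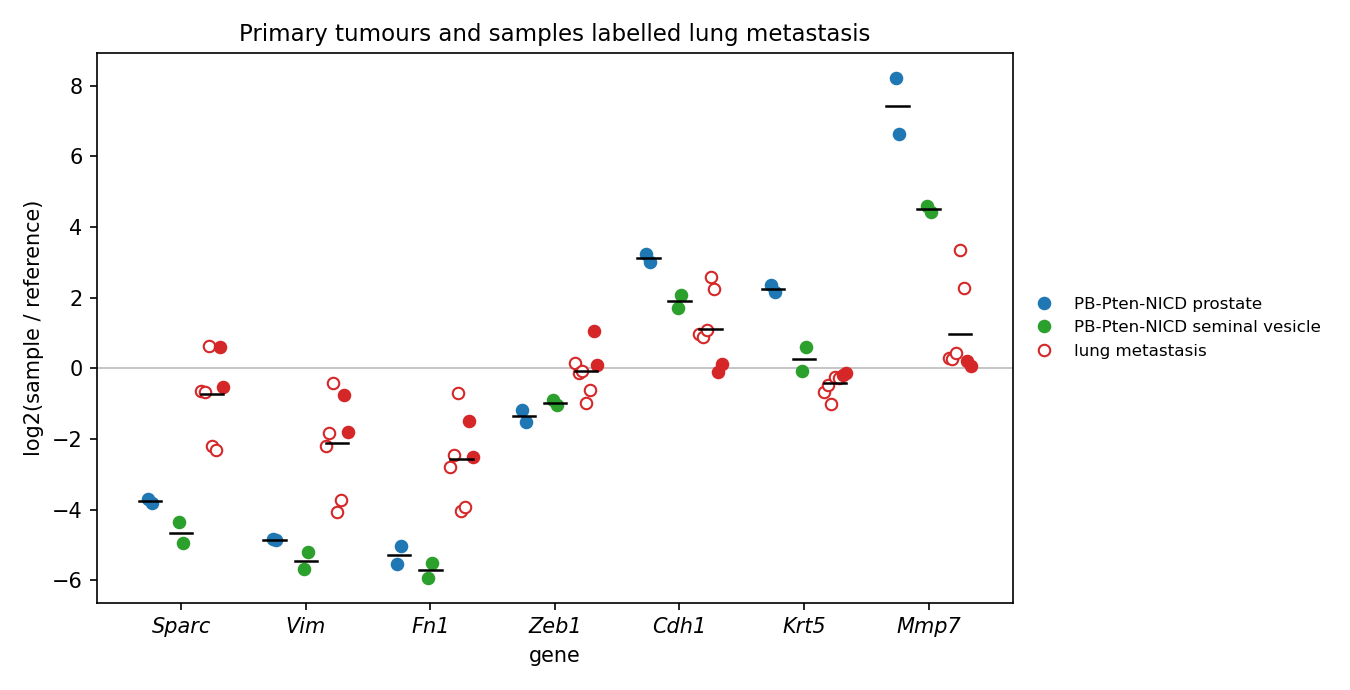
Log2 ratio of sample to reference (vertical axis) of 7 genes (horizontal axis) in the PB-Pten-NICD prostates, seminal vesicles and samples labelled lung metastasis. Each point is a sample, filled on slide 1 and open on slides 2 and 3, and each bar a group mean. Vim averaged -5.14 over the 4 primary tumours and -2.11 over the 7 metastases, with an SD of 1.37 after arrays labelled as 1 sample were averaged.

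In total 2230 genes rose and 503 fell among 34324 tested (9327 at an unadjusted p under 0.05). On slide 1 alone 1048 rose and 212 fell, and of the 2563 called genes tested there 544 were called again. With metastases 3 and 5 and metastases 4 and 6 averaged and counted once each, 137 rose and 48 fell, and with the arrays averaged by slide position, 4 and 8 (positions shared by metastasis 7 and PtNI-SV were left out). In the sample channel alone 156 rose and 500 fell. With slide as a fixed block, which takes the difference from metastases 1 and 2 alone, 832 genes passed. With the mean of the lung epithelium list as a covariate 21 passed. That mean, which includes Cyp2f2, itself differed by -0.47 from the prostates and 0.20 from the seminal vesicles, so this count does not single out lung tissue. The 2733 genes became 20 without seminal vesicle 1 or 2, 168 without PB-Pten-NICD prostate 2, 208, 192 and 1609 without metastases 3, 5 and 1, and 5182 without metastasis 2.

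Against the PB-Pten-NICD prostates alone, the samples labelled lung metastasis had 183 genes higher and 170 lower (limma, 6465 at an unadjusted p under 0.05). Mmp7 fell by -6.44 ± 0.77 (log2 difference ± SE, adjusted p = 0.00211), Crisp1 by -5.69 ± 0.71, Pate4 by -5.44 ± 0.67, Akr1b7 by -5.39 ± 0.52, Cyp2f2 by -5.19 ± 0.56, Spink8 by -5.01 ± 0.85, Wfdc15b by -4.51 ± 0.68 and Cxcl17 by -4.26 ± 0.23 (adjusted p = 3.13e-06). Higher were Tm4sf1 (3.76 ± 0.72), Csrp2 (at least 4.70-fold), the cyclophilin Ppic (2.52 ± 0.47), Col1a1 (2.40 ± 0.44), the thrombin receptor F2r (2.39 ± 0.45), the nucleoside transporter Slc29a1 (2.13 ± 0.42), Got1 (2.13 ± 0.32) and Nes, nestin (2.12 ± 0.44). Vim differed by 2.73 ± 0.78 (adjusted p = 0.0972), Zeb1 by 1.28 ± 0.39 (adjusted p = 0.110) and Cdh1 by -2.02 ± 0.57 (adjusted p = 0.0946).

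Among the lists, 3 of 20 epithelial genes fell (Dsp, -1.71 ± 0.30, Esrp2, -1.35 ± 0.28, and Ocln, -1.24 ± 0.27) and 10 when adjusted over the list alone. Of the prostate luminal list 2 of 14 genes fell, Hoxb13 (-2.80 ± 0.27) and Nkx3-1 (-0.88 ± 0.17), and 5 when adjusted over the list alone. Of the secretory list 3 of 8 fell and 4 when adjusted over the list alone. Of the basal list 1 of 12 fell (Krt5, -2.68 ± 0.29) and 4 when adjusted over the list alone. Of the interferon list 1 of 10 fell (Ifit3, -2.15 ± 0.38) and 3 when adjusted over the list alone. Of the proliferation list 1 of 22 rose (Bub1, at least 1.63-fold) and 9 when adjusted over the list alone. The camera adjusted p of these 6 lists were 3.04e-10, 0.0138, 1.12e-05, 0.00108, 0.000299 and 1.12e-05. The adjusted p with an estimated correlation were 0.198, 0.198, 0.158, 0.158, 0.228 and 0.228. By slide position 0, 1, 1, 1, 0 and 0 of their genes passed over all genes. EMT transcription factors (0 of 9, 7 higher when adjusted over the list alone, Snai1 with a bound of at least 2.64-fold), hypoxia genes (0 of 12) and immediate early genes (0 of 11, Egr1 at 1.60) passed as higher and squamous genes (0 of 14, 3 lower when adjusted over the list alone, Krt6a at -1.51) as lower. Their camera adjusted p were 1.24e-05, 0.0155, 0.0273 and 0.00225, and the adjusted p with an estimated correlation were 0.198, 0.366, 0.252 and 0.198. The lung epithelium list also passed as lower (camera adjusted p = 0.0393, and adjusted p = 0.219 with an estimated correlation), with 1 of 15 genes lower, Cyp2f2, and 4 lower and 1 higher when adjusted over the list alone. By fry 9 lists passed, with mesenchymal genes, which camera left out, at an adjusted p = 0.0333, and by slide position 2 did, seminal vesicle secretory and basal genes (adjusted p = 0.0347 each), with mesenchymal genes at 0.143. Of 22 mesenchymal genes 1 rose and 1 fell over all genes, and 12 rose and 2 fell when adjusted over the list alone. List means changed sign with the lung epithelium covariate for EMT transcription factors (-0.095), epithelial genes (0.24), prostate luminal genes (0.026) and immediate early genes (-0.092). That covariate, the mean of a list that holds Cyp2f2, was itself lower than in the prostates (-0.47), so these changes do not single out lung tissue. List means also changed sign in the sample channel alone for hypoxia and glycolysis genes (-0.084), and under the strict background filter for prostate luminal genes (0.14).

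On slide 1 Mmp7 was at least 135-fold, Cyp2f2 at least 49.5-fold and Cdh1 at least 6.93-fold lower, and Tm4sf1 and Vim were higher by 3.21 and 3.56, each past the test there, while Col1a1 did not pass (1.66, adjusted p = 0.112). Of the lists that passed camera over all arrays, proliferation, hypoxia and lung epithelium genes did not pass on slide 1 (camera adjusted p = 0.120, 0.176 and 0.120). The others did. On slide 1 alone 1169 genes passed in this comparison, 98 with the metastases of matching profiles averaged and 30 with arrays averaged by position. Leaving out 1 sample gave 89, 82, 561, 630, 184 and 797 genes without metastases 3, 5, 7, 4, 1 and 2, 106 and 217 without PB-Pten-NICD prostate 1 and 2, and 126 and 123 without seminal vesicle 1 and 2.

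Against the PB-Pten-NICD seminal vesicles alone, 0 genes passed in limma, with 7463 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0579. The largest of the named differences were Sparc at 3.92 ± 0.69 (adjusted p = 0.0591), Col1a1 at 3.47 ± 0.44, Vim at 3.33 ± 0.78 (adjusted p = 0.0665) and Fn1 at 3.16 ± 0.70, with Heyl at a bound of at least 2.37-fold (adjusted p = 0.181) and Pten at 1.11 ± 0.39. Of 22 mesenchymal genes 11 were higher when adjusted over the list alone (median 1.71, or 1.08 with genes not above background at their bounds), of 12 hypoxia genes 5 (median 0.86, Ldha at 2.40) and of 22 proliferation genes 4 (median 0.60, Cdc20 at 1.66). Interferon genes lay at a median of 0.47 (2 of 10 higher when adjusted over the list alone), EMT transcription factors at 0.73 (0.41 at the bounds) and epithelial genes at -0.58. These 6 lists passed camera at adjusted p = 0.00447, 0.00193, 0.000494, 0.0296, 0.0131 and 0.0107, and each had an adjusted p = 0.699 with an estimated correlation. By slide position the interferon list did not pass camera (adjusted p = 0.0737). By fry 1 list passed, mesenchymal genes (adjusted p = 0.0317), which did not pass by slide position (0.193). On slide 1 Vim was higher by 4.16 (adjusted p = 0.000984) and Heyl at least 7.83-fold. Proliferation and interferon genes did not pass camera there (adjusted p = 0.137 and 0.660, interferon median 0.06). The other lists of these 6 did. On slide 1 alone 599 genes were higher and 90 lower, and the software's own log ratios gave 1519 genes. Without metastasis 2, 7, 4 or 6 or seminal vesicle 1, the count was 2336, 260, 54, 5 or 4.

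The comparison of the 3 cell lines with the lung metastases set samples labelled as cultured lines against samples labelled as metastases. Since the arrays of metastasis 7 matched those of PtNI-SV, and those of PtNI-Pro matched PtNI-Met, the groups may share a sample and the lines may not be 3 separate samples, and the values below hold only under the labels. No gene passed in limma (0 of 35101, 3162 at an unadjusted p under 0.05, smallest adjusted p 0.457). Myeloid markers were lower in the lines, at a median of -1.02 (14 genes, 0 over all genes and 7 when adjusted over the list alone), with Lyz2, lysozyme, at -2.75 ± 0.60 (log2 difference ± SE, n = 3 and 7), Tyrobp at -2.19 ± 0.41 and C1qa at -2.16 ± 0.50. Red blood cell markers had a median of -3.17 (-2.31 with genes not above background at their bounds, 5 genes, 3 lower when adjusted over the list alone), with Hba-a1, alpha globin, at -3.86 ± 1.23. The camera adjusted p were 3.12e-06 and 0.0264, and the adjusted p with an estimated correlation were 0.404 and 0.916. Proliferation genes (median 0.31, Mcm5 at 0.74 ± 0.36) and interferon genes (median -0.38, Irf7 at -1.22 ± 0.36, 1 of 10 lower when adjusted over the list alone) passed camera at 0.0233 and 0.0264, with an adjusted p = 0.916 with an estimated correlation. The proliferation mean was 0.27 with all arrays and -0.16 with technical replicate 1 only, and 0 lists passed by fry (smallest adjusted p 0.0571). Hey1 differed by 1.08 ± 0.52, Heyl by -1.53 ± 0.68, Vim by 0.19 ± 0.78 and Cdh1 by -0.48 ± 0.49, with adjusted p from 0.546 to 0.958. Without metastasis 7 the count was 378 and without PtNI-SV 246, and with arrays averaged by slide position 6 genes were higher. By slide position red blood cell, proliferation and interferon genes did not pass camera (adjusted p = 0.179, 0.179 and 0.168).

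Each cell line was labelled as a single sample, so differences among the lines carry no test. Arrays of PtNI-Pro matched those of PtNI-Met at r = 0.93 and 0.79, so these may not be separate samples. The 2 arrays labelled PtNI-SV correlated at -0.22, those of PtNI-Pro at 0.55 and those of PtNI-Met at 0.48. The differences hold only under the labels. Cd24a, a surface glycoprotein, lay 3.17 above the mean of the other lines on the log2 scale in PtNI-SV, with ratios of 2.78 and 4.80 on its 2 arrays. Cst9 lay at -2.37 there, from array ratios of 3.57 and -3.13, a gap of 6.70 between arrays labelled as replicates of 1 line. Artn, the neurotrophic factor artemin, lay 1.66 above the others in PtNI-Pro (1.92 and 3.23 on its arrays). Hmgb2, a chromatin protein, lay 1.90 above them in PtNI-Met (3.12 and 3.31).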

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

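The tests of the array labels and of the seminal vesicle secretory genes, and the values of both channels and of the strict filter for the genes higher in seminal vesicle, were chosen only after those results were seen. Among 50 genes examined in the 7 samples labelled lung metastasis, 2 had a sample far from the others. This is no more than chance gives, at about 1 in 20 genes. Ube2c, a ubiquitin-conjugating enzyme of mitosis, was at a log2 ratio of -1.98 in metastasis 2 against -0.51 to -0.18 in the others. Nrarp was at 4.46 in metastasis 7 against 1.37 to 2.37 in the others, a mean of 2.09 and 6.82 on its arrays, of which the latter lay at the position where PtNI-SV gave 5.74.

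A pattern to follow up is the disagreement of arrays labelled as technical replicates on slides 2 and 3. An effect of array position is argued against by slide 1, where arrays at the same position as on slides 2 and 3 correlated by -0.0225 more than arrays at different positions. Correct labels with similar samples at the same positions are argued against by slide 1, where different samples of 1 group correlated at 0.71 or more, while arrays labelled as replicates of 1 sample reached at most 0.684. The same 8 samples lying at the same positions on both slides remains a candidate explanation, since 8 of 8 arrays matched that way. No group was inferred from expression, although Lyz2, a myeloid marker, had log2 sample signals of 11.2 and 10.3 on array 1 of metastasis 7 and PtNI-SV and was not above background on array 2 of either (6.88 and 6.82). Acta2 had log2 sample signals of 16.1, 15.8, 14.9 and 14.5 on array 2 of metastasis 7, PtNI-SV, PtNI-Pro and PtNI-Met. On array 1 of these it was at 9.73, 9.76, 9.33 and 9.35. The averages under these labels therefore mix unlike arrays.

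The seminal vesicle secretory genes that rose in the PB-Pten-NICD prostates raise the question of tissue from outside the prostate. Tissue like these seminal vesicle tumours is argued against, since the list was lower in them than in the prostates, with a median difference of -2.02 against a spread between samples of 0.419. The reference channel or the normalization is argued against by the sample channel alone, where the list's median difference was 2.87. Normal seminal vesicle tissue, a different share of prostate lobes or an effect of active Notch1 may each contribute, and these were not tested.

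Of the 53 genes higher in seminal vesicle than in prostate tumours, 100% were above background on both seminal vesicle arrays, against 62.7% of all genes tested. Genes picked as higher there would tend to be. These flags do not test dim arrays acting through the background offset or the normalization. With normexp offset 10 the count of 105 genes in both directions was 355. Signals near background are argued against for 52 of the 53, which were above background in both channels on each of the 6 arrays. Requiring that of all genes left 0 calls in limma (2231 at an unadjusted p under 0.05), with the 52 still tested at an unmoved median difference of 2.03 (median standard error 0.313 before and 0.308 after) and a smallest adjusted p of 0.0580. In the sample channel alone 18 of the 53 (34.0%) differed by 1 or more, 49 lay above 0 and 1 passed, so the reference channel or the normalization remains a candidate explanation for part of them. Other probes of 18 of these genes had a median difference of 0.08. The difference in tissue stays open and untested.

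For the lung metastases against primary tumours, 1 of 100 splits of the 11 samples, the real one, gave as many as 2733 genes, and the highest other split gave 4. Chance can be excluded as far as the samples are exchangeable, which the shared slide of all primary samples and the matching profiles of metastases 3 and 5 and of 4 and 6 put in doubt. For the cell lines against metastases the splits say nothing about chance, since with a real count of 0 genes each of the 100 splits must give as many. The highest other split, of metastases 7 and 1 and PtNI-SV from the rest, gave 6524, which points to a structure of the samples, and arrays of metastasis 7 and PtNI-SV at the same positions correlated at 0.91 and 0.91.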

How the results depend on the processing

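The fits that averaged arrays by slide position or merged metastases 3 with 5 and 4 with 6 were chosen only after the results were seen, and the other settings were planned. The cause of each change was not tested, unless stated. For PB-Pten-NICD against PB-Pten prostate (8 higher, 1 lower), the count was 23 (15 and 8) with median centring, 7 (7 and 0) with the software's log ratio, 2 when both channels had to be above background on every array, 5 with the mean of a gene's probes, 5 with only the groups compared and 3 with the replicate block, and 5 to 48 with 1 sample left out. For seminal vesicle against prostate (53 higher, 52 lower), it was 355 with normexp offset 10, 547 (77 and 470) with median centring, 569 with the software's log ratio, 31 (1 and 30) in the sample channel alone, 0 under the strict filter, 3 with the mean of probes, 45 without a trend, 14 in a fit of all 16 samples, 681 with only the groups compared and 4 with the replicate block, and 1 to 724 with 1 sample left out. Median centring moved the median of all genes there from 0.04 to -0.19, and that of the cell line comparison from -0.04 to 0.19, and the called differences are relative to it. Under the strict filter, with both channels above background on every array, 4 of the 9 and 73 of the 105 called genes were still tested.

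For metastases against primary tumours (2230 higher, 503 lower), the count was 653 with median centring, 656 (156 and 500) in the sample channel alone, 1776 with technical replicate 1 only, 1007 with the replicate block, 832 with slide as a fixed block, 1260 on slide 1 (fewer samples), 21 with the lung epithelium covariate, 12 by slide position and 185 with metastases merged (both with fewer samples), and 20 to 5182 with 1 sample left out. It was 2250 with slide as a random block. Against prostate (183 higher, 170 lower), it was 690 without background correction, 106 with offset 10, 71 (17 and 54) with median centring, 45 (6 and 39) with the software's log ratio, 74 (2 and 72) in the sample channel alone, 581 (361 and 220) with the deposited table, 1 under the strict filter, 148 without a trend, 116 with technical replicate 1, 130 with only the groups compared, 826 with the replicate block, 702 with slide as a fixed block, 1169 on slide 1, 3 with the lung covariate, 30 by slide position and 98 merged, and 82 to 797 with 1 sample left out.

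Against seminal vesicle (0 genes in limma, 7463 at an unadjusted p under 0.05), the count was 331 without background correction, 833 with offset 10, 25 with median centring, 1519 with the software's log ratio, 333 with the deposited table, 680 under the strict filter, 668 with technical replicate 1, 343 with the replicate block, 271 with slide as a fixed block, 689 on slide 1 and 218 with the lung covariate, and 0 to 2336 with 1 sample left out. For cell lines against metastases (0 genes in limma, 3162 at an unadjusted p under 0.05), it was 6 by slide position (8 samples, without the positions shared by metastasis 7 and PtNI-SV), 0 in the other settings without an omitted sample, and 0 to 378 with 1 sample left out.

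List means and genes that changed sign were prostate luminal genes under the strict filter, at 0.017 for PB-Pten-NICD against PB-Pten prostate and 0.14 for metastases against prostate, and smooth muscle genes without PB-Pten-NICD prostate 1, at -0.026 in the former comparison (0.87 without PB-Pten-NICD prostate 2) and 0.087 for seminal vesicle against prostate (-0.81 without PB-Pten-NICD prostate 2). In the sample channel alone Twist2 was at -0.030 for metastases against primary tumours, and hypoxia and glycolysis genes at -0.0843 for metastases against prostate. With the lung covariate, metastases against prostate had EMT transcription factors at -0.10, epithelial genes at 0.24, prostate luminal genes at 0.026 and immediate early genes at -0.092. The covariate itself differed between these groups (-0.47), so these changes do not single out lung tissue. With technical replicate 1 only, proliferation genes were at -0.16 for cell lines against metastases. Over named genes and lists, 4472 results under these settings stayed on their side of the threshold (called ones in the same direction, the others within a standard error), 989 kept direction but no longer passed, 57 newly passed, 11 changed sign and 241, of genes without a call, moved by more than their standard error.

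The labels do not say that a number in a title marks an animal, so the replicate block rests on a shared number only. In the comparisons of metastases with primary tumours, all but metastases 1 and 2 shared a block without primary samples. The difference there comes from metastases 1 and 2 alone, as with slide as a fixed block. Deviations of same-numbered samples from their group means correlated at -0.59 for PB-Pten and PB-Pten-NICD prostate, 0.42 for PB-Pten prostate and seminal vesicle and -0.19 for PB-Pten-NICD prostate and seminal vesicle. Among the primary samples, signal over background limits dim genes most in the seminal vesicles, where 45.5% to 58.8% of probes were well above background. Metastases 1 and 2, which carry the slide 1 results, had 42.4% and 56.3%, and array 2 of metastasis 4 had 41.8%.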

Other observations

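No test in this part was chosen after its result was seen, but slide 1 values are given for lists picked after they were seen. Gene groups that did not pass in the metastases against primary tumours included single genes that did. Of 9 neuroendocrine genes 1 rose over all genes, Eno2 (1.05 ± 0.21, log2 difference ± SE), a neuronal enolase, and 1 when adjusted over the list alone, with Ascl1 at -0.69 ± 0.33 (median -0.13, camera adjusted p = 0.640). Of 11 inflammatory cytokines the monocyte chemokines Ccl7 (1.21 ± 0.28) and Ccl2 (0.88 ± 0.24) rose, 2 over all genes and 2 when adjusted over the list alone, with Lcn2 at -1.13 ± 0.61 (median 0.01, camera adjusted p = 0.833). Of 12 endothelial genes 1 rose, Tie1 (at least 1.19-fold), and 1 when adjusted over the list alone (median 0.37, camera adjusted p = 0.571). On slide 1 the endothelial list passed, with 3 of 11 genes higher and 4 when adjusted over the list alone (median 0.51, camera adjusted p = 0.00798, adjusted p = 0.0229 by fry, and adjusted p = 0.305 with an estimated correlation). Of 12 basal epithelial genes Krt5 and Krt15 (-1.44 ± 0.37) fell, 2 over all genes and 3 when adjusted over the list alone (median -0.35, camera adjusted p = 0.0574). The basal list passed as lower on slide 1 (median -0.61, camera adjusted p = 0.00798, and adjusted p = 0.305 with an estimated correlation). There 2 of 11 genes fell over all genes and 3 when adjusted over the list alone.

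Between metastases and primary tumours immune markers had medians of -0.05 for lymphocytes (12 genes, camera adjusted p = 0.571) and 0.14 for myeloid cells (14 genes, camera adjusted p = 0.884, with the test in the lower direction), and 0 genes of either list passed in limma. On slide 1 2 of 14 myeloid genes were higher over all genes and 2 when adjusted over the list alone, and the list did not pass (median 0.40, camera adjusted p = 0.330). Skeletal muscle markers lay at a median of 0.27 for PB-Pten-NICD against PB-Pten prostate (7 genes, camera adjusted p = 0.0851) and -0.18 for seminal vesicle against prostate (7 genes, camera adjusted p = 0.382), and 0 genes passed in limma.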
